A study of Mus musculus and Rattus norvegicus with 12 samples.

How the data were processed

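RNA-seq counts of 12 cell lines were analysed, 8 from mouse and 4 from rat. The samples were separately derived lines, so replicate spread here is the spread between lines. Groups were taken from the titles and cell types given in the labels: 3 mouse pXEN lines, 3 mouse XEN lines, 2 mouse ES lines and 4 rat XENP lines. The count tables of the 3 pXEN lines are named as mouse XENP with the same line numbers, while titles and cell types say pXEN. Per the labels' protocols, ribosomal RNA was depleted from total RNA and strand-specific libraries were made with a directional kit and sequenced as paired ends.

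The authors deposited whole-number counts per gene, 1 table per line, in 3 columns that hold unstranded counts, counts on the gene's own strand and counts on the reverse strand, per the file headers and values. CASAVA 1.8.2, Trimmomatic 0.33, STAR 2.5.1 and DESeq2 (no version) and the genome builds mm10 and rn6 are named in the submitters' processing notes, without the role of each. The annotation used for counting is not given in the sources used here. The reverse-strand column was used, because it held 98.9% to 99.3% of the stranded counts in the mouse lines and 99.1% to 99.2% in the rat lines. The unstranded column was an alternative.

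Rows for read classes (unmapped, multimapping, no feature, ambiguous) were left out of library sizes and tests. They held 73.4% to 78.3% of all reads in the mouse tables, of 11253421 to 13792878 reads per line, and 89.7% to 91.8% in the rat tables, of 11943246 to 13138414. Multimapping reads made up 7.84% to 9.65% in mouse and 65.5% to 70.1% in rat. Genes with near-identical copies may therefore have lost reads, which were not traced, and counts for paralogs such as Rpl39l are uncertain. The row of the ribosomal RNA precursor Rn45s took 20.7% to 50.1% of mouse gene counts and 0.00821% to 0.0312% of rat gene counts. It stayed in the tests, and its removal was tried as an alternative.

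Of 24411 mouse symbols, 23376 matched the GENCODE vM21 annotation of GRCm38, from which gene coordinates are given. No rat genome or annotation was used here, and rat genes carry the symbols of the deposited tables.

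Differences between mouse groups were tested with edgeR 4.0.16 under R 4.3.3. All 8 mouse libraries were fitted together with TMM scaling, filterByExpr by group (minimum count 10), robust glmQLFit and glmQLFTest, and 10895 genes were tested. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, and 0.05 was the threshold. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. Mouse levels are edgeR's CPM of the TMM-scaled library and rat levels CPM of all gene counts without TMM scaling, given as mean ± SD over lines. Because Rn45s took a far larger share of mouse counts, rat and mouse CPM are not on one scale. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group (0.299 CPM in pXEN, 0.302 in XEN and 0.600 in ES). With 1 to 3 counts the level is given, or a ratio with its exact 95% counting interval. Such intervals and floors cover counting error only, since reads of PCR-amplified libraries are not independent molecules.

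The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The 28 lists were: pluripotency, primed epiblast, pan-extraembryonic endoderm, parietal endoderm, visceral endoderm, anterior visceral endoderm, trophoblast, fibroblast (for feeder cells), blood and endothelium, epithelial, mesenchymal, basement membrane, FGF/ERK targets, LIF/STAT3 targets, Wnt targets, Nodal and BMP targets, cholesterol synthesis, glycolysis and hypoxia, cell cycle, DNA methylation machinery, germline genes, imprinted genes, endocytosis and lysosome, endoplasmic reticulum stress, interferon response, antigen presentation, p53 targets and sex-linked genes. Each list was tested against all other genes with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation. As an alternative it was tested against no change with fry. Each test was adjusted over the 28 lists. Members past the threshold were counted over all genes and adjusted over the list alone.

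The genes named in each comparison are anchor genes fixed in advance, the 8 highest and 8 lowest fold changes among called genes without overlap between groups and with at least 10 CPM in the higher group, and up to 4 called members per list, or up to 2 with the smallest p where no member was called. Some genes that the rule names are not reported here. Genes named outside this rule are stated to have been chosen after their values were seen.

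Rat and mouse counts were not tested gene by gene against each other, since species, genome, annotation and group change together. Spearman's rho of CPM was computed between each rat and each mouse line over 11245 shared symbols, of 14387 symbols present in both species, and mean similarity to the mouse groups was compared by an exact relabelling of mouse lines. A signature score was the mean expression percentile of genes called higher in pXEN than XEN minus that of genes called lower.

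The scripts were tested on simulated data with known changes. In counts simulated for pXEN against XEN (10484 genes tested), 43 of 47 genes changed 8-fold were recovered, 33 of 50 changed 4-fold, 8 of 48 changed 2-fold and 0 of 49 changed 1.5-fold, with 2 calls among 10290 unchanged genes. For pXEN against ES (10381 genes) the shares were 91.5%, 58.3%, 4.17% and 2.22%, and for XEN against ES (10531 genes) 88.0%, 64.6%, 8% and 0%. Changes below 4-fold were thus often missed in these simulations. They held far fewer changed genes than the comparisons with ES called, so the shares may understate recovery there.

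Alternatives were relative log expression and upper-quartile scaling, 2 other filters, DESeq2 1.42.0, unstranded counts, sex as a covariate, fits of the compared groups alone, other similarity measures and leaving out each line in turn. Removal of Rn45s, and rat comparisons without genes near 0 counts in pXEN, were added after the data were seen. Spearman's rho across genes between replicate lines was 0.897 to 0.966. Each line was counted as a replicate because the labels give it as a separate derivation.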

Results

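Gene expression was measured in 12 lines to compare extraembryonic endoderm cells of mouse and rat. The mouse lines were of the ICR strain: pXEN2, pXEN4 and pXEN6, XEN1, XEN2 and XEN5, and the embryonic stem (ES) lines ES2 and ES3. XEN cells are stem cell lines of the primitive endoderm, the blastocyst lineage that gives rise to yolk sac endoderm, and ES cells are pluripotent lines. The pXEN lines were kept in the conditions used for the rat XENP lines (CX1 and MAX8 from WKY rats, MAX2 and MAX3 from F344 rats). XEN lines grew on mouse embryo fibroblast feeders in serum, and ES lines in serum with LIF and a pair of kinase inhibitors. Cell type and culture condition therefore differed together in each mouse comparison.

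Counts assigned to genes totalled 2661691 to 3483069 per mouse line and 1047535 to 1242937 per rat line. The ribosomal RNA precursor Rn45s took 20.7% to 40.0% of them in pXEN, 27.1% to 39.4% in XEN and 38.5% to 50.1% in ES, which left 1635626 to 2418423 other counts per mouse line. Between 12190 and 14319 genes were detected in a mouse line and 10033 to 10311 in a rat line.

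Sex-linked transcripts mostly followed the labelled sex of the lines, apart from low Xist in the female ES line and transcripts of the other sex at low levels in the 3 XEN lines. Y-linked genes summed to 163 CPM in the male line pXEN2, 193 in XEN2, 356 in XEN5 and 271 in ES2. Among female lines, pXEN4 had 0 Y-linked counts, pXEN6 had 1, ES3 had 1 and XEN1 had 22 (95% Poisson interval 13.8 to 33.3). Xist, the RNA that silences an X chromosome, reached 784 CPM in pXEN4, 659 in XEN1 and 150 in pXEN6 but 14.0 CPM in female ES3. Males XEN2 and XEN5 had 34 and 33 Xist counts (9.45 and 8.72 CPM), and males pXEN2 and ES2 had 0 and 1. In the rat, Eif2s3y had 414 and 255 counts in the males CX1 and MAX3 and 0 in both female lines.

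The comparisons with ES cells asked how far pXEN and XEN lines carry an endoderm program. Endoderm regulators were higher, and pluripotency genes lower, in both kinds of line than in ES. Gata6, which specifies primitive endoderm (chromosome 18, 11052064 to 11085635, plus strand, GRCm38), stood at 105 ± 14.3 CPM in pXEN (SD, n = 3) and 85.7 ± 17.3 in XEN (n = 3) with 0 counts in ES (n = 2). It was at least 174-fold higher in pXEN and at least 143-fold higher in XEN (adjusted p = 3.02e-06 and 3.21e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its relative Gata4 was 249-fold higher in pXEN (log2 fold change 7.96, SE 0.44, adjusted p = 1.65e-06) and 247-fold in XEN. The endoderm factor Sox17 was 400-fold and 264-fold higher, Pdgfra, a growth factor receptor of primitive endoderm, 77.3-fold and 80.6-fold, and Sox7 45.6-fold and 45.9-fold. Foxa2, Aqp8 and Bmper had 0 ES counts, and Aqp8, a water channel, reached 180 ± 4.16 CPM in pXEN and 220 ± 91.0 in XEN.

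The pluripotency factor Nanog fell from 905 ± 292 CPM in ES to 1 count over the 3 pXEN lines and 1 count over the 3 XEN lines (adjusted p = 1.05e-06 and 1.08e-06). Sox2 had 0 counts in both and was at least 728-fold lower in pXEN and at least 722-fold lower in XEN. Esrrb and Tdgf1 likewise had 0 counts in both groups, against 279 ± 2.93 and 348 ± 35.6 CPM in ES. Pou5f1, which encodes Oct4, fell 39.4-fold in pXEN, from 905 ± 131 to 22.8 ± 14.5 CPM (log2 fold change -5.30, SE 0.45, adjusted p = 2.19e-05), and to 2 counts in XEN. Zfp42 (Rex1) was 44.7-fold lower in pXEN than its ES level of 726 ± 138 CPM. Of 30 measured pluripotency genes, 25 fell and 1, Klf4, rose in each comparison (2 rose in pXEN adjusted over the list alone, camera adjusted p = 3.82e-37 for pXEN and 5.90e-41 for XEN, and 0.000886 and 0.00371 with an estimated correlation).

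In all, 1978 genes were higher and 1936 lower in pXEN than in ES, with 4963 at an unadjusted p under 0.05. In XEN 2251 were higher and 1937 lower than in ES, with 5211 at that level. With upper-quartile scaling lower genes outnumbered higher ones, 1792 higher and 2183 lower in pXEN and 2039 higher and 2270 lower in XEN. Without ES2 the higher genes numbered 1168 for pXEN and 1277 for XEN, and the lower genes for XEN 1197. Without ES3 the XEN counts were 1463 and 1262. The 2 groups of libraries did not overlap for 62.8% and 63.3% of all genes, where chance gives 20%. Both comparisons called 1672 of the same genes higher and 1464 lower, where independent lists would share 409 higher genes, and 17 genes went in opposite directions. Without ES2 the shared higher genes numbered 953. The same ES libraries served both comparisons. Libraries simulated with no changed gene in any group, ES included, shared 0 calls (20 simulations). Such data give few calls in either comparison, so this does not measure what the shared libraries add. Fold changes correlated across genes at 0.856 (0.630 in simulation), with covariance 4.53 against 0.192, a difference of 4.34. The ES lines were not divided between the comparisons, and part of this overlap may come from the shared libraries.

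**Figure D1:**
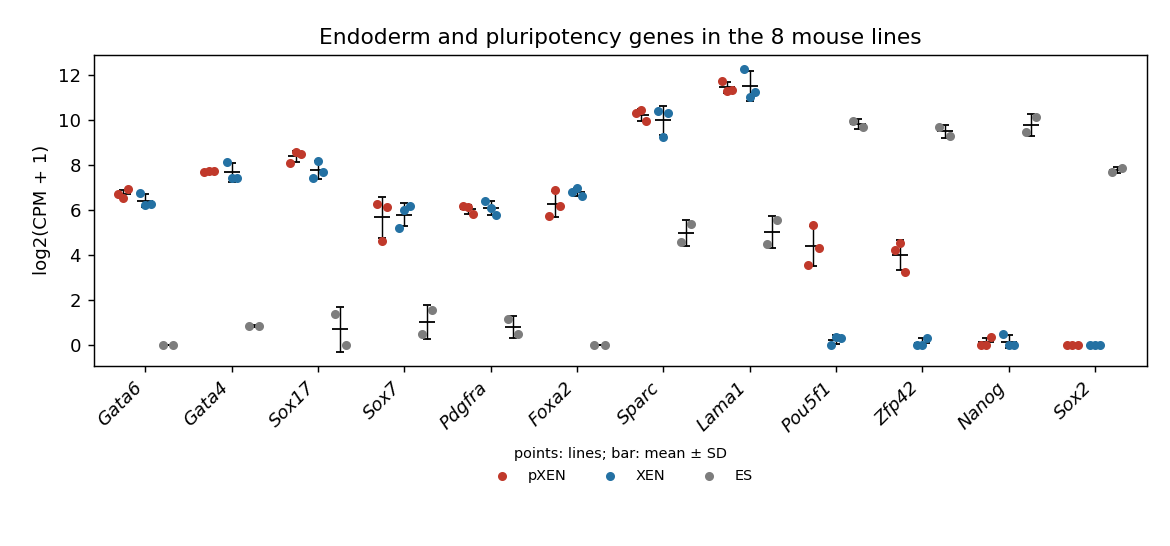
Log2(CPM + 1) of 12 anchor genes, endoderm markers from Gata6 to Lama1 and pluripotency genes from Pou5f1 to Sox2, in the mouse lines. Points are single lines, bars are means with SD (pXEN red, XEN blue, ES grey), and Pou5f1 lies at 22.8 CPM in pXEN between 905 CPM in ES and 2 counts in XEN.

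Most members of the pan-extraembryonic endoderm, parietal endoderm and basement membrane lists were higher than in ES. In the pan-extraembryonic endoderm list 15 of 18 measured genes were higher in pXEN and 16 in XEN than in ES (camera adjusted p = 3.38e-21 and 1.76e-22, and 0.0209 and 0.0173 with an estimated correlation). The parietal endoderm list, genes of the matrix-secreting endoderm, had 17 of 21 higher in each (20 and 18 adjusted over the list alone, camera adjusted p = 3.38e-21 and 5.22e-18, and 0.0337 and 0.0388 with an estimated correlation). Sparc, a matrix glycoprotein, rose 38.1-fold and 34.0-fold from 31.6 ± 12.7 CPM, the laminin chain Lama1 84.4-fold and 93.0-fold from 33.7 ± 16.8 CPM, and Pth1r 536-fold and 372-fold. Thbd, a parietal marker, had 54.4 ± 24.0 CPM in pXEN and 52.3 ± 74.9 in XEN against 3 counts in ES and did not pass (adjusted p = 0.0522 and 0.0520). Of 23 basement membrane genes 18 were higher and 4 lower in pXEN (Col18a1, Lama5, Agrn, Fbln1) and 19 higher and 2 lower in XEN (Col18a1, Lama5), with camera adjusted p = 1.32e-13 and 4.82e-16 and, with an estimated correlation, adjusted p = 0.0602 and 0.0388. Lamb1, a laminin chain, rose 211-fold and 192-fold from 15.1 ± 6.52 CPM in ES.

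The visceral endoderm list, genes of the absorptive yolk sac layer, had 9 of 14 higher in pXEN and 10 in XEN and Apoc1 and Apoe lower in both (camera adjusted p = 0.0023 and 0.00127, and 0.227 and 0.238 with an estimated correlation). Cubn, an uptake receptor, stood at 234 ± 196 and 432 ± 304 CPM against 3 ES counts, and Hnf4a was 5.27-fold and 6.19-fold higher. Ttr, a thyroxine carrier, had 11.8 ± 11.5 and 14.6 ± 10.0 CPM against 1 count (adjusted p = 0.0188 and 0.0139) and lost both calls without ES2 or without ES3 (adjusted p up to 0.131 and 0.107). Afp had 4 counts in pXEN, 7 in XEN and 0 in ES and was not tested. Endocytosis and lysosome genes rose with them, 16 of 25 in each comparison (17 adjusted over the list alone, with 1 lower in pXEN, camera adjusted p = 2.28e-07 and 1.01e-06, and 0.184 and 0.170 with an estimated correlation). The adaptor Dab2 was 219-fold and 265-fold higher and the protease Lgmn 20.7-fold and 18.0-fold. Endoplasmic reticulum stress genes had 11 of 20 higher and Trib3 lower in pXEN and 15 higher in XEN (16 adjusted over the list alone, camera adjusted p = 0.0023 and 2.76e-05, and 0.210 and 0.0934 with an estimated correlation), among them the chaperone partner Dnajc3 at 7.20-fold and 5.71-fold.

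Several lists of other early embryonic genes had more lower than higher members. The anterior visceral endoderm list had 5 of 6 measured genes lower in each (Lefty1, Nodal, Otx2, Sfrp1 and Fzd5), and Dkk1 higher in XEN (camera adjusted p = 1.49e-07 and 2.04e-06, and 0.0216 and 0.0388 with an estimated correlation). The 5 lower genes are expressed in ES cells as well, and Nodal fell from 95.9 ± 17.6 CPM to 0 counts in pXEN and 1 in XEN. Primed epiblast genes had 5 of 7 lower in pXEN (6 adjusted over the list alone) and 6 in XEN, Otx2, Foxd3, Pou3f1, Zic2 and Zic5 in both and Dnmt3b in XEN (camera adjusted p = 0.000839 and 0.00100, and 0.0602 and 0.0531 with an estimated correlation). In XEN the Pou3f1 and Zic2 calls were lost without ES2 or without ES3 (adjusted p up to 0.104 and 0.0995), and that of Zic2 also without XEN1 or XEN5. The DNA methylation machinery had 5 of 10 lower in pXEN (6 adjusted over the list alone) and 7 in XEN, with Tet3 higher in both (camera adjusted p = 0.000826 and 3.80e-05, and 0.0602 and 0.0388 with an estimated correlation). Tet1, which oxidises methylcytosine, was 27.0-fold and 22.9-fold lower, Zfp57, which guards imprints, 17.8-fold and 16.0-fold, and Tet2, Uhrf1 and Trim28 were also lower in pXEN. Germline genes had 6 of 7 lower in each, with 1 higher in pXEN adjusted over the list alone (camera adjusted p = 0.000764 and 5.08e-05, and 0.0672 and 0.0388 with an estimated correlation). Imprinted genes were mixed, with 3 of 25 higher (Airn, Gnas, Sfmbt2) and 11 lower in pXEN (camera adjusted p = 0.0259, and adjusted p = 0.127 with an estimated correlation) and 7 higher and 7 lower in XEN (9 and 8 adjusted over the list alone, camera adjusted p = 0.570).

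Signalling target lists moved less evenly. Nodal and BMP targets had 3 of 15 higher (Bmp2 and Bambi among them) and 7 lower in pXEN (4 and 8 adjusted over the list alone, camera adjusted p = 0.0162, and adjusted p = 0.196 with an estimated correlation). In XEN, 2 were higher, Bmp2 among them, and Lefty1, Lefty2 and Nodal lower (camera adjusted p = 0.202). FGF/ERK targets had 8 of 16 lower in pXEN (camera adjusted p = 0.00149, and adjusted p = 0.217 with an estimated correlation), with Etv5 35.4-fold lower. In XEN, Etv1, Etv4, Etv5 and Ccnd1 were lower and the immediate early genes Fos and Egr1 higher (camera adjusted p = 0.344), and the Egr1 call was lost without ES2 or without ES3 (adjusted p up to 0.151). Wnt targets had 4 of 7 lower in pXEN (Notum, Tnfrsf19, Tcf7, Znrf3, camera adjusted p = 0.0197, and adjusted p = 0.131 with an estimated correlation). The Znrf3 call was lost without pXEN4, pXEN6 or ES3 (adjusted p up to 0.180). In XEN, Notum and Tnfrsf19 were lower and Sp8 and Dkk1 higher (3 lower adjusted over the list alone, camera adjusted p = 0.297), but the latter 2 calls were lost without ES2 or without ES3 (adjusted p up to 0.217), and that of Dkk1 also without XEN1 or XEN2. LIF/STAT3 targets split 7 higher and 5 lower of 14 in pXEN and 6 and 5 in XEN (camera adjusted p = 0.732 and 0.655). Lifr, the LIF receptor, rose 13.3-fold in pXEN, and Socs2 fell 41.3-fold in pXEN and 17.5-fold in XEN.

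Genes of fibroblasts separated XEN from the other mouse groups. Of 19 measured fibroblast genes 17 were higher in XEN than in ES (camera adjusted p = 1.55e-13, and 0.0388 with an estimated correlation). In pXEN against ES only Tagln was higher and Thy1 and Col5a2 lower (camera adjusted p = 0.864), and without ES3 the Tagln call and without ES2 the Col5a2 call was lost (adjusted p = 0.0671 and 0.188). The difference between these comparisons is the pXEN and XEN comparison itself. Mesenchymal genes had 7 of 11 higher in XEN (8 adjusted over the list alone, camera adjusted p = 0.000219, and 0.0496 with an estimated correlation), against 3 higher (Snai1, Vim, Itga5) and 4 lower (Fn1, Cdh2 and Mmp2 among them) in pXEN (4 and 4 adjusted over the list alone, camera adjusted p = 0.323). Among epithelial genes Krt8, Krt18 and Esrp2 rose in both and Krt19 in pXEN, while Cdh1 and Cldn4 fell in both and Grhl2 and Spint1 in XEN (camera adjusted p = 0.506 and 0.918). DESeq2 did not call Cdh1 (adjusted p = 0.116 and 0.119) or, in XEN, Cldn4 (0.110).

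Of the other lists only interferon response passed camera in pXEN against ES. Trophoblast genes had Tead4 higher and Eomes and Esrrb lower in both and Tfap2a lower in XEN (2 higher in pXEN adjusted over the list alone, camera adjusted p = 0.124 for pXEN and 0.00517 for XEN, where adjusted p = 0.0705 with an estimated correlation). Without ES2 the Eomes call in pXEN (adjusted p = 0.0502) and the Tead4 call in XEN (0.0785) were lost, and the Tfap2a call was lost without XEN2, XEN5, ES2 or ES3 (up to 0.127). Cell cycle genes had 7 of 28 lower in pXEN and 9 in XEN (camera adjusted p = 0.325 and 0.0375, and in XEN 0.614 with an estimated correlation). Without XEN1, XEN5 or ES2 the XEN call was lost. Cholesterol synthesis had 7 of 23 higher and Idi1 lower in pXEN and 2 higher (Insig1, Stard4) and 9 lower in XEN (10 adjusted over the list alone, camera adjusted p = 0.302 and 0.0965). Glycolysis and hypoxia genes had 3 of 26 higher (P4ha1, Vegfa, Egln3) and 6 lower in pXEN (4 and 6 adjusted over the list alone) and 8 and 3 (Pfkp, Pdk1, Kdm3a) in XEN (camera adjusted p = 0.707 and 0.297). Interferon response genes had Bst2, Ddx58 and Ifitm3 lower in both (camera adjusted p = 0.0391 in pXEN, where adjusted p = 0.320 with an estimated correlation and the call was lost without pXEN2 or pXEN4, and 0.0675 in XEN). For antigen presentation B2m was 4.18-fold and 5.63-fold higher (camera adjusted p = 0.365 and 0.297). In the p53 list Trp53 was 6.60-fold and 6.38-fold lower, Perp, Trp53inp1 and Zmat3 were also lower and Ccng1 higher in pXEN (3 lower adjusted over the list alone), and Cdkn1a, Btg2, Bbc3, Phlda3 and Ccng1 were higher in XEN (camera adjusted p = 0.243 and 0.655). For blood and endothelium Cdh5 and Tek were higher and Pecam1 lower in both and Cd68 lower in pXEN (Pecam1 in XEN not by DESeq2, adjusted p = 0.0597, and 2 lower in XEN adjusted over the list alone, camera adjusted p = 0.852 and 0.918). Of the sex-linked genes Tsix was lower in both (camera adjusted p = 0.365 and 0.655). Calls for Cdh5, Tek, Cd68, Idi1, Insig1, Pdk1, Ccng1, Bbc3 and Bst2 were each lost in at least 1 of these comparisons without ES2 or without ES3 (adjusted p up to 0.266).

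In the comparisons with ES, counts adjusted over the list alone equalled those over all genes wherever no other count is given. The sign of the median, the mean and the test differed for the fibroblast, trophoblast, epithelial and mesenchymal lists in pXEN and for the epithelial, LIF/STAT3, Wnt, Nodal and BMP and sex-linked lists in XEN. Klf4, Apoe, Fzd5, Zic5, Dnmt3b, Krt18, Esrp2, Spint1, Vim, Itga5, Agrn, Fbln1, Bambi, Airn, Gnas, Trib3, Uhrf1, Trim28, Kdm3a, Phlda3 and Zmat3 were named after their values were seen, to give the members of small counts, as were Lama5, Sfmbt2, Etv4, Vegfa, Egln3, Tet3, Ccnd1, Stard4, Pdk1, Ccng1 and Col18a1 in at least 1 comparison.

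The comparison of pXEN with XEN asked how endoderm lines kept in rat XENP conditions differ from conventional XEN lines. In pXEN 2 pluripotency regulators, Pou5f1 and Zfp42, were higher, while matrix genes of fibroblasts and mesenchyme were much lower and core endoderm regulators did not differ detectably. Pou5f1 (chromosome 17, 35506018 to 35510772, plus strand, GRCm38) had 235 counts over the pXEN lines, 22.8 ± 14.5 CPM (SD, n = 3), and 2 counts over the XEN lines, a ratio of 116 (95% counting interval 31.9 to 967, log2 fold change 6.58, SE 0.72, adjusted p = 0.000832, edgeR's quasi-likelihood test). Zfp42 (chromosome 8, 43295063 to 43306980, minus strand) stood at 16.2 ± 6.93 CPM against 1 count (adjusted p = 0.000258). Lox, an enzyme that crosslinks collagen (chromosome 18, 52516067 to 52529867, minus strand), had 0 counts in pXEN and 269 ± 82.2 CPM in XEN, at least 898-fold lower (adjusted p = 1.49e-05).

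Of 10895 genes 100 were higher and 396 lower in pXEN, so 20.2% of called genes were higher, and 1652 had an unadjusted p under 0.05. DESeq2 called 155 higher and 476 lower. Without XEN1, 63 were higher, and without pXEN2, 255 were lower. The groups differ in sex, with 1 male pXEN and 2 male XEN lines, and with sex as a covariate 68 genes were higher and 320 lower, with 362 of the 496 calls kept. The 3 pXEN and 3 XEN lines did not overlap for 19.8% of all genes, where chance gives 10%, and for all 496 called genes. Of the 396 lower genes 96 had 0 pXEN counts and 196 had 3 or fewer. Against ES, 43 of the 100 higher genes were also higher in pXEN, 13 were lower and 44 did not differ by the test. Of the 396 lower genes 177 were also below ES, 23 above and 196 not different by the test.

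**Figure D2:**
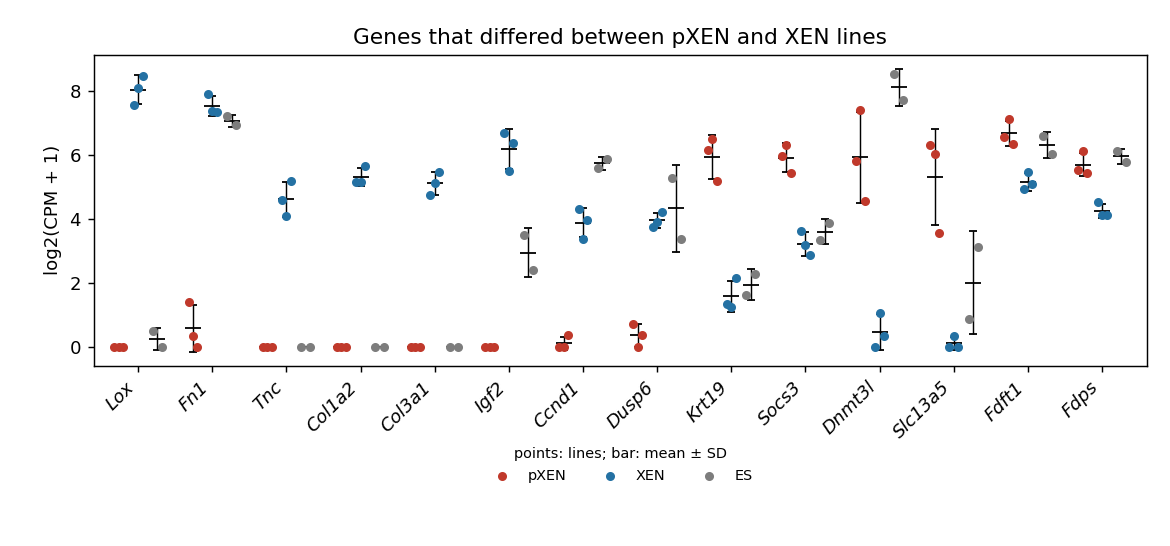
Log2(CPM + 1) of 14 genes called between pXEN and XEN, with points for single lines and bars for means with SD (pXEN red, XEN blue, ES grey). Lox, Col1a2, Col3a1 and Igf2 had 0 counts in pXEN, and Krt19, Socs3, Dnmt3l and Slc13a5 were higher in pXEN than in XEN.

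Core endoderm regulators were not called between pXEN and XEN, a comparison in which simulated 2-fold changes were mostly missed. Gata6 stood at 105 ± 14.3 CPM in pXEN and 85.7 ± 17.3 in XEN (log2 fold change 0.29, SE 0.22, adjusted p = 0.629), Gata4 at 210 ± 5.34 and 208 ± 62.0, and Sox17 at 337 ± 57.0 and 222 ± 62.5 (adjusted p = 0.421). Sox7 stood at 56.5 ± 28.6 and 56.5 ± 18.4 CPM, Pdgfra at 65.0 ± 8.62 and 67.9 ± 15.0, Foxa2 at 80.8 ± 33.5 and 111 ± 12.9, and Hnf4a at 30.7 ± 11.3 and 36.2 ± 4.24. Of 18 pan-extraembryonic endoderm genes only Runx1 was called, 7.12-fold lower in pXEN (adjusted p = 0.0319, camera adjusted p = 0.412), and its call was lost without pXEN2, pXEN6 or any XEN line (up to 0.121). Of 21 parietal endoderm genes edgeR called 0 over all genes (5 at an unadjusted p under 0.05, 2 by DESeq2), and 2 were higher adjusted over the list alone (camera adjusted p = 0.0598), with Tfpi at 495 ± 232 against 152 ± 64.2 CPM and Nrk at 10.8 ± 8.33 against 2.07 ± 0.858. Sparc, Lama1 and Thbd stood at 1207 ± 202, 2850 ± 508 and 54.4 ± 24.0 CPM in pXEN and 1077 ± 414, 3142 ± 1584 and 52.3 ± 74.9 in XEN. Of 14 visceral endoderm genes edgeR called 0 in either count (3 at an unadjusted p under 0.05, 1 by DESeq2, camera adjusted p = 0.618). There Dpp4 stood at 18.3 ± 16.5 against 65.2 ± 23.2 CPM, Slc39a8 at 33.7 ± 12.8 against 67.8 ± 15.1 and Ttr at 11.8 ± 11.5 against 14.6 ± 10.0. In the anterior visceral endoderm list Fzd5 was 3.76-fold lower (2 of 6 lower adjusted over the list alone, camera adjusted p = 0.133), a call lost without pXEN2 (adjusted p = 0.0566). Cdx2 had 1 count in each group and was not tested.

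The pluripotency list as a whole did not pass camera (adjusted p = 0.0774) but passed fry (adjusted p = 0.0338). Pou5f1, Zfp42 and Dppa5a were higher among 30 measured members (4 higher and 3 lower adjusted over the list alone), while Nanog had 1 count in each group and Sox2 had 0. Dppa5a had 14 counts, 1.36 ± 1.05 CPM, against 0 in XEN, at least 4.51-fold, and its call was lost without pXEN4 or any XEN line (adjusted p up to 0.0801). Dnmt3l, a cofactor of de novo DNA methylation (chromosome 10, 78041947 to 78063622, plus strand), stood at 81.9 ± 76.1 CPM against 0.459 ± 0.581 (log2 fold change 7.25, SE 1.11, adjusted p = 0.0117), and without XEN1 its adjusted p was 0.0618. It was the only called member of 10 in the DNA methylation machinery (2 higher adjusted over the list alone, camera adjusted p = 0.249). Of 7 primed epiblast genes edgeR called 0 (2 at an unadjusted p under 0.05, 1 by DESeq2) and 1 was higher adjusted over the list alone (camera adjusted p = 0.618), with Dnmt3b at 74.2 ± 19.5 against 33.1 ± 14.6 CPM. Of 7 germline genes edgeR called 0 (1 at an unadjusted p under 0.05, 1 by DESeq2) and 1 was higher adjusted over the list alone (camera adjusted p = 0.279), with Asz1 at 14.2 ± 15.6 CPM against 1 count and Rpl10l at 2 counts against 0. Trophoblast genes were higher as a list (5 measured, camera adjusted p = 0.0161), but adjusted p = 0.167 with an estimated correlation and the call was lost without pXEN2 or pXEN6. There Tfap2a had 3.02 ± 1.40 CPM against 1 count (2 higher adjusted over the list alone), a call lost without XEN2 or XEN5 and with sex as a covariate (adjusted p up to 0.113), and Eomes had 8 counts against 2.

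Fibroblast genes were the group that differed most in its test. Of 19 measured members 16 were lower in pXEN (17 adjusted over the list alone, camera adjusted p = 4.27e-66, and 0.00241 with an estimated correlation), with a median log2 fold change of -6.80, or -4.84 with genes at 0 counts set to their bound. Col1a2, a chain of type I collagen (chromosome 6, 4504814 to 4541544, plus strand), had 0 pXEN counts against 39.3 ± 8.29 CPM, at least 132-fold lower, and Col3a1 0 against 34.1 ± 8.54 CPM, at least 114-fold. Col1a1 had 1 count against 36.9 ± 6.02 CPM (adjusted p = 5.91e-05), and Col5a2, Prrx1 and Ogn had 0 counts. Mesenchymal genes followed, 6 of 11 lower (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 1.54e-23, and 0.00241 with an estimated correlation). Fn1 (fibronectin) fell 288-fold from 186 ± 42.8 CPM (log2 fold change -8.17, SE 0.54, adjusted p = 2.38e-05) and the matrix protease Mmp2 54.6-fold from 29.3 ± 3.07 CPM. Cdh2 and Zeb2, also lower, were named after their values were seen. The XEN lines were the only ones described as cultured on fibroblasts, and the female line XEN1 held 22 Y-linked counts where the other female mouse lines held 0 to 1. In ES cells Fn1 stood at 133 ± 17.5 CPM. The growth factor gene Igf2 (chromosome 7, 142650766 to 142666816, minus strand) had 0 pXEN counts against 75.3 ± 29.2 CPM, at least 252-fold lower, and the matrix protein Tnc 0 against 24.7 ± 9.75.

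Of the signalling target lists, those of FGF/ERK, Wnt and Nodal and BMP were lower in pXEN by camera with the preset correlation, and each lost its call with an estimated correlation. Ccnd1, Dusp6, Sp8 and Bmp4 had 3 or fewer pXEN counts, as most fibroblast genes did, so RNA of feeder cells in XEN is not excluded for them. Ccnd1 and Sp8 divided over the XEN lines otherwise than the fibroblast list (adjusted p = 0.00102 each, chi-square test by simulation), as did 3 of 14 fibroblast genes. Dusp6 and Bmp4 did not (0.926 and 0.139), but genes at an even level over the XEN lines would divide much alike, so this does not point to feeders. The FGF/ERK target list had 4 of 16 lower (6 adjusted over the list alone, camera adjusted p = 1.66e-07, and adjusted p = 0.151 with an estimated correlation). Ccnd1, a cyclin of the cell cycle start, had 1 count against 14.2 ± 4.63 CPM (adjusted p = 0.000213), the ERK phosphatase Dusp6 3 counts against 14.6 ± 2.56 CPM, and Spred1 was 17.3-fold lower (log2 fold change -4.11, SE 0.53). Etv4 was 2.72-fold lower (adjusted p = 0.0421), a call lost without any of the other lines than pXEN4 (up to 0.149). Wnt targets had Sp8 lower (3 of 7 adjusted over the list alone, camera adjusted p = 0.00682, and adjusted p = 0.151 with an estimated correlation), with 1 count against 18.6 ± 24.1 CPM, mostly from XEN2 (8, 167 and 24 counts in XEN1, XEN2 and XEN5). The list's call was lost without XEN2 and that of Sp8 without any pXEN line (adjusted p up to 0.244). Nodal and BMP targets had Bmp4, Smad7 and Skil lower and Id4 higher of 15 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0338, and adjusted p = 0.263 with an estimated correlation), and the list's call was lost without pXEN2, pXEN6, XEN1 or XEN2 and with sex as a covariate. Bmp4 had 0 counts against 5.31 ± 2.35 CPM. Calls were lost for Smad7 without pXEN2 (adjusted p = 0.0597), for Skil without pXEN4, pXEN6, XEN1 or XEN5 (up to 0.150) and for Id4 without pXEN2, pXEN6 or any XEN line (up to 0.125). LIF/STAT3 targets did not move together (camera adjusted p = 0.876, 4 of 14 higher and 6 lower adjusted over the list alone). The feedback inhibitor Socs3 (chromosome 11, 117966079 to 117970047, minus strand) was 7.16-fold higher in pXEN, 60.8 ± 18.4 against 8.57 ± 2.52 CPM (log2 fold change 2.84, SE 0.33, adjusted p = 0.000808), and the receptor Osmr 4.40-fold lower, a call lost without pXEN4, pXEN6 or any XEN line (up to 0.132).

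The endoplasmic reticulum stress, p53 and glycolysis and hypoxia lists were lower by camera with the preset correlation, and each lost its call with an estimated correlation. Endoplasmic reticulum stress genes had Atf3, Herpud1 and Ppp1r15a lower of 20 (5 adjusted over the list alone, camera adjusted p = 0.0241, and adjusted p = 0.383 with an estimated correlation), and the list's call was lost without pXEN4 or XEN2 and with sex as a covariate. Atf3, a stress-induced transcription factor, fell 19.5-fold from 138 ± 42.2 CPM (log2 fold change -4.29, SE 0.50, adjusted p = 0.00133), Herpud1 2.72-fold and Ppp1r15a 3.37-fold, the last not called without pXEN2 (adjusted p = 0.0556). Among 16 genes of the p53 list Cdkn1a, Bbc3 and Perp were lower (6 adjusted over the list alone, camera adjusted p = 0.000103, and adjusted p = 0.263 with an estimated correlation). Bbc3, which promotes cell death, fell 4.29-fold. The cell cycle inhibitor Cdkn1a fell 2.77-fold from 201 ± 78.3 CPM, but its call was lost without pXEN2, XEN1 or XEN5 (up to 0.0723), and that of Perp without pXEN2, pXEN6, XEN1 or XEN2 (up to 0.0713). Glycolysis and hypoxia genes had Egln3, an oxygen sensor, 3.49-fold lower (2 of 26 adjusted over the list alone, camera adjusted p = 0.00028, and adjusted p = 0.263 with an estimated correlation). Interferon genes had Ifitm3 lower (1 of 6 measured in both counts, camera adjusted p = 0.412), with 1 count against 5.04 ± 1.73 CPM.

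Of 23 cholesterol synthesis genes 5 were called, all higher in pXEN (15 adjusted over the list alone, camera adjusted p = 1.44e-10, and adjusted p = 0.171 with an estimated correlation). Fdft1, which makes squalene (chromosome 14, 63145150 to 63179578, minus strand), rose 2.93-fold to 103 ± 29.5 CPM from 35.0 ± 7.21 (log2 fold change 1.55, SE 0.27, adjusted p = 0.00758), and Fdps, which makes its precursor, 2.85-fold to 51.7 ± 14.0 CPM. Sqle and Dhcr7 rose 2.74-fold and 2.34-fold, Sqle not called without pXEN2, pXEN4, XEN1 or XEN5 (adjusted p up to 0.101) and Dhcr7 not without pXEN6, XEN1 or XEN5 (up to 0.0879).

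Single genes of other kinds were higher. Krt19, a simple epithelial keratin (chromosome 11, 100140810 to 100148665, minus strand), rose 29.0-fold to 64.3 ± 27.0 CPM from 2.13 ± 1.13 (log2 fold change 4.86, SE 0.47, adjusted p = 0.000245). It was the only called epithelial gene of 16 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.407). Slc13a5, a citrate transporter (chromosome 11, 72241989 to 72267222, minus strand), had 51.1 ± 35.6 CPM against 1 count (adjusted p = 0.0102), not called without any XEN line (up to 0.0944), and Rinl 19.8 ± 14.0 CPM against 3 counts, likewise (up to 0.0763). Tnni3 had 13.7 ± 15.2 against 0.408 ± 0.417 CPM, likewise (up to 0.0993), and Rpl39l, whose paralogs may share reads, 21.7 ± 18.0 against 0.441 ± 0.294 CPM. In the imprinted list Sfmbt2 (chromosome 2, 10370510 to 10595253, plus strand) was 3.22-fold higher and Igf2 lower (1 higher and 7 lower of 25 adjusted over the list alone, camera adjusted p = 0.00028, and adjusted p = 0.0638 with an estimated correlation). The Sfmbt2 call (adjusted p = 0.0476) was lost without any of the lines but XEN2 (up to 0.154).

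The remaining lists held few or no called genes. Basement membrane genes had Lama5 6.08-fold and Fbln1 19.6-fold lower of 23 (3 lower adjusted over the list alone, camera adjusted p = 0.131), and the Fbln1 call was lost without pXEN2, pXEN4, XEN1 or XEN2 (adjusted p up to 0.108). Of 28 cell cycle genes edgeR called 0 in either count (2 at an unadjusted p under 0.05, 1 by DESeq2), and they were higher as a list (camera adjusted p = 0.0334, and adjusted p = 0.606 with an estimated correlation), a call lost without pXEN2, XEN1 or XEN5, with Plk1 at 125 ± 10.0 against 66.4 ± 21.2 CPM and Aurka at 119 ± 21.0 against 84.3 ± 10.0. No call over all genes or adjusted over the list alone was made by edgeR among 5 blood and endothelial genes (camera adjusted p = 0.779), 25 endocytosis and lysosome genes (0.608), 6 antigen presentation genes (0.716) or 6 sex-linked genes (0.407). At an unadjusted p under 0.05 these lists held 1, 3, 0 and 0 genes, and DESeq2 called 0 in each. There Cdh5 stood at 221 ± 145 against 59.3 ± 41.8 CPM, Psap at 764 ± 224 against 427 ± 140, B2m at 58.3 ± 21.5 against 78.7 ± 15.9 and Kdm5d at 1.75 ± 3.04 against 5.47 ± 8.77. In this comparison the signs of median, mean and test differed for the blood and endothelium, LIF/STAT3, endocytosis and lysosome and DNA methylation lists.

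**Figure D3:**
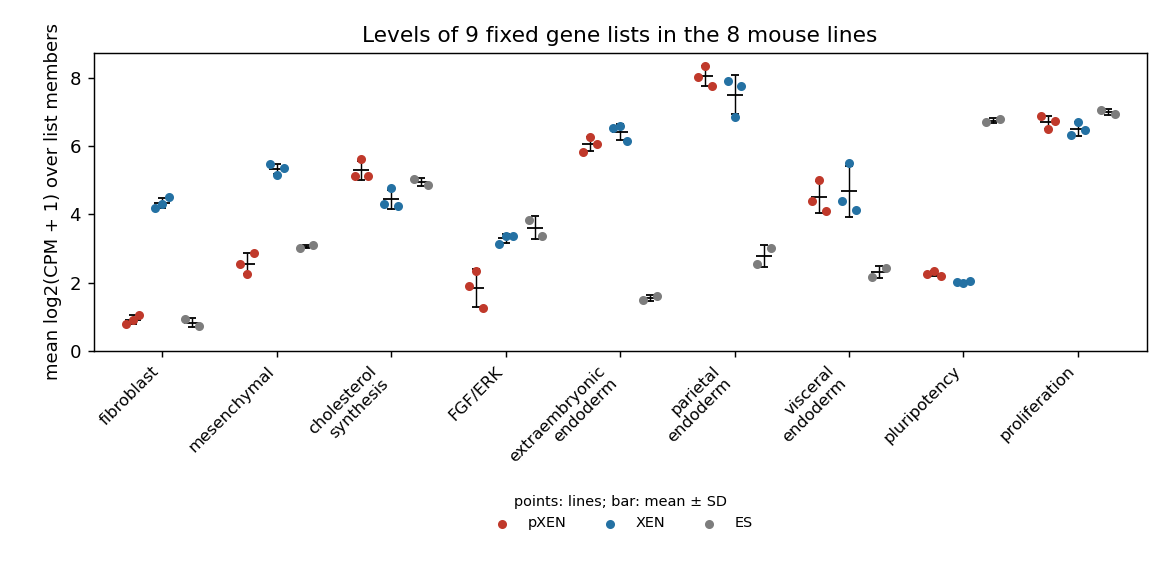
Mean log2(CPM + 1) over the measured members of 9 gene lists, with points for single mouse lines and bars for means with SD (pXEN red, XEN blue, ES grey). Fibroblast and mesenchymal lists lie lower in pXEN than in XEN, with 16 of 19 and 6 of 11 members called lower, while pluripotency is highest in ES.

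The rat lines were compared with each mouse group to ask which one XENP cells resemble most. Over 11245 shared genes, mean Spearman's rho of the 4 rat lines across genes was 0.763 with pXEN (SD over rat lines 0.00723), 0.747 with XEN (0.0063) and 0.679 with ES (0.0178). Similarity to pXEN exceeded that to XEN by 0.0160 ± 0.00151 (SD, n = 4), with pXEN ahead in 4 of 4 rat lines (two-sided exact permutation p = 0.1, the smallest that the 20 relabelings of mouse lines allow). It exceeded that to ES by 0.0842 ± 0.0112 (exact p = 0.1, the smallest of 10). Without genes with 3 or fewer pXEN counts that were called lower, the lead over XEN was 0.00928, and among only the genes called between pXEN and XEN it was 0.214. Genes are not independent replicates, and species, genome and annotation differ together between the compared lines. The pXEN lines also shared the culture condition of the rat lines, while XEN lines grew on fibroblasts in serum and ES lines in serum with LIF. The lead of pXEN may therefore come from culture, or over XEN from feeder RNA, as well as from cell type. These were not told apart.

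On a score that subtracts the mean percentile of 200 genes lower in pXEN from that of 83 genes higher, rat XENP lines lay at 20.8 ± 2.20 percentile points (SD, n = 4), between pXEN at 44.1 ± 0.856 and XEN at -12.9 ± 1.15. ES lines lay at 17.4 ± 1.69, and XENP exceeded them by 3.43 (two-sided exact permutation p = 0.133 over 15 splits, with 2.28 without genes near 0 counts in pXEN and 6.23 with 50 genes per direction). The genes were chosen on the mouse lines, so the mouse pXEN and XEN scores are not independent evidence. Of 337 genes lower in pXEN, 66.2% had a rat percentile nearer to pXEN than to XEN, and of 83 higher genes 45.8%, against 51.9% of 8376 other genes.

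**Figure D4:**
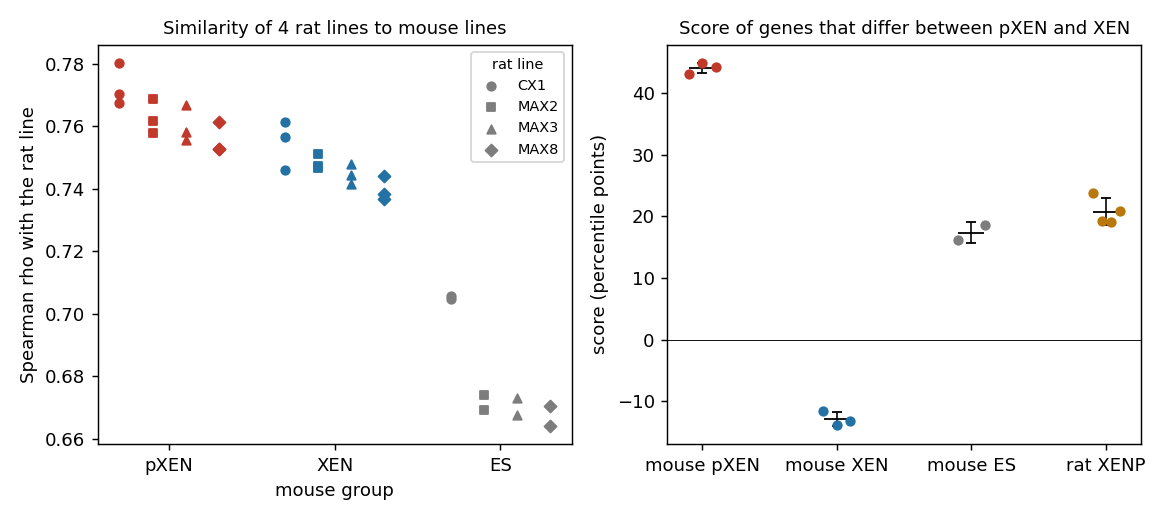
Left, Spearman's rho across genes between each rat XENP line and each mouse line, by mouse group, with means of 0.763 (pXEN), 0.747 (XEN) and 0.679 (ES). Right, the score in percentile points for each mouse and rat line, with XENP at 20.8 between XEN and pXEN.

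Rat XENP lines expressed most of the named endoderm regulators and lacked the fibroblast collagens, while their endoderm lists ranked below those of mouse pXEN and XEN. Gata6 stood at 248 ± 57.3 CPM (SD, n = 4), Gata4 at 957 ± 209, Sox17 at 925 ± 256, Pdgfra at 478 ± 163, Sox7 at 12.9 ± 5.97, Foxa2 at 87.2 ± 22.3 and Hnf4a at 12.8 ± 12.9, with 1 Hnf4a count in MAX8. Parietal markers were abundant, with Sparc at 11940 ± 3971 CPM, Lama1 at 7020 ± 1785 and Thbd at 663 ± 156. Col1a1, Col1a2, Col3a1, Prrx1, Ogn, Tnc and Col5a2 had 0 counts in all 4 lines, and the fibroblast list lay at a median percentile of 7.85 in XENP, 8.35 in pXEN, 54.7 in XEN and 10.1 in ES. In the same order the pan-extraembryonic endoderm list lay at 54.8, 85.8, 88.4 and 11.9. The parietal endoderm list lay at 81.6, 96.8, 94.2 and 27.2, and the visceral endoderm list at 21.2, 39.7, 45.4 and 12.9. Annotation, multimapping reads and gene counts differ between the species, so lower list ranks need not reflect the cells. Anchor endoderm genes went both ways. Gata6, Gata4, Sox17, Pdgfra, Thbd, Sparc and Lama1 ranked higher in XENP than in pXEN or XEN, and Sox7, Foxa2, Hnf4a, Ttr and Afp lower. Fn1 and Ccnd1, which were near 0 in pXEN, stood at 30.7 ± 8.75 and 38.4 ± 15.7 CPM, on a scale that differs from that of mouse CPM. Krt19 stood at 142 ± 60.0 CPM, Socs3 at 99.2 ± 34.3 and Id4 at 231 ± 96.9. Nanog, Sox2, Slc13a5, Tfap2a, Afp and Cdx2 had 0 counts in the rat. Pou5f1 stood at 163 CPM in CX1 and at 6.25 to 8.32 CPM in the other rat lines, and a rat value for Zfp42 is not reported here.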

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

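The test on RNA of genes with over 3 pXEN counts, the test on Y-linked counts and the tests on Pou5f1 in pXEN and in CX1 were chosen after the results were seen. The test on genes near 0 counts in pXEN and the splits of the mouse lines were planned before.

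In XEN, fibroblast collagens and other matrix genes were high where pXEN had 0 to 3 counts, and the XEN lines had been cultured on fibroblasts, so RNA of feeder cells is a candidate source. If it were the only source for genes with 3 or fewer pXEN counts, these genes would divide over XEN1, XEN2 and XEN5 as the fibroblast list does. Of 184 such genes 28.8% departed from that division, but so did 3 of 14 fibroblast genes themselves (21.4%), which leaves the source open. The fibroblast list divided 20.4%, 35.5% and 44.1% over these lines. Their TMM-scaled library sizes were 2566211, 3596716 and 3784939. Genes at an even level in the XEN cells themselves would divide by library size, which is not far from this. Agreement with the fibroblast division therefore does not point to feeders. Among 200 lower genes with over 3 pXEN counts, 3.50% had an excess in XEN above the highest of any fibroblast gene (Acta2, 183 CPM): among them Fn1, and Rpph1, Thbs1, Malat1, Jun and Klf6, the last 5 named after their values were seen. This met the bound set for feeder RNA, which is permissive, and Thbs1 (1124 CPM in XEN, 96.7 in pXEN, not called without pXEN6, adjusted p = 0.0617), Jun (280 and 37.6) and Klf6 (328 and 89.1) are genes that many cell types express.

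Y-linked genes had 22 counts in female XEN1, against an upper limit of 5.57 from the other female lines. Males XEN2 and XEN5 had 34 and 33 Xist counts where males pXEN2 and ES2 had 0 and 1, so transcripts of the other sex were present in all 3 XEN lines, a comparison made after the values were seen. The Y-linked count prompted the test on RNA of other cells, so it adds no support for that source. Set against the male lines it would equal a male share of 2.41% to 5.25%, and whether it came from feeders, from other cells or from reads of other libraries stays open. A difference of the XEN cells themselves and of serum or feeder signals stays open too, because culture and cell type change together, and the tests do not tell which lower genes come from feeders.

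Pou5f1 and Zfp42 were higher in pXEN than in XEN, which ES-like cells in the cultures or reads from the ES libraries could also produce. Such cells would bring other pluripotency transcripts at the share that Pou5f1 sets. Over 15 such genes with 3 or fewer XEN counts, the pXEN lines together held 2.17% of the needed count, with 4 counts in pXEN2 where 122 were needed, 9 in pXEN4 where 513 were needed and 6 in pXEN6 where 242 were needed (upper limits 10.2, 17.1 and 13.1). This argues against ES-like cells or ES reads as the whole source. An earlier form of the test, run first and replaced, took the pooled level of 23 genes as a share of ES: 0.911%, 0.824% and -0.331% against 1.18%, 4.29% and 2.04% for Pou5f1. By it pXEN2, at 0.772 of the Pou5f1 share, was not below the bound of 1 in 5, and its sum also held genes with over 3 counts in XEN. Low expression of Pou5f1 and Zfp42 in pXEN cells remains as a hypothesis, with culture condition as an untested cause.

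In rat line CX1, Pou5f1 stood at 163 CPM where the other rat lines had 6.25 to 8.32 CPM. ES-like cells in the culture could bring it, but of Nanog, Sox2, Esrrb, Fgf4 and Utf1 only Utf1 had a count, 1, where 338 were needed (upper limit 5.57). This test for ES-like cells argues against them only as far as the mouse ratio of these genes to Pou5f1 holds in rat. It also assumes that the rat rows of these genes collect reads, which no pluripotent rat line here could show. Nanog, Sox2, Esrrb and Fgf4 had 0 counts in all 4 rat lines. Passage number, highest in CX1, and a difference of this line itself were not tested and stay open.

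Other values in CX1 lay far from the rest. Dnmt3l stood at 98.2 CPM (0 to 1.91 in the others), Dnmt3b at 175 (49.1 to 64.7), Sfmbt2 at 46.7 (0.893 to 2.77), Aurka at 244 (132 to 149) and Slc39a8 at 12.1 (0.924 to 1.79). Runx1 at 4.02 CPM (0 in the others) and Rpl39l at 3.22 (0.893 to 0.955) rest on few counts. The mean Spearman's rho of CX1 across genes with the mouse ES lines was 0.705 (0.667 to 0.672 in the others). In MAX8, Pecam1, an adhesion gene of endothelium, stood at 238 CPM (43.9 to 72.1). In MAX3, Ttr stood at 2.86 CPM (0 in the others), and in MAX2 Lox at 0.924 CPM, from 1 count, with 0 in the others. The germline list lay at a median percentile of 7.94 in MAX2 (17.5 to 19.1), which is the percentile of genes with 0 counts in that line. A test for a single distant sample among the 4 rat lines picked these 13 values out of 100 tested. Its rate of 1 in 20 groups by chance, or 5, assumes values without ties, so the 13 cannot be set against it. Where the other lines had 0, any value is picked, as for Ttr, Lox and Runx1.

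The split of the 6 mouse pXEN and XEN lines into their groups gave 100 higher genes, 396 lower genes and 12 lists past the threshold. The other splits gave at most 3 genes in 1 direction, counted for either because swapping the 2 groups swaps the direction. With the preset correlation 4 to 11 lists passed in them, so lists also passed under every other grouping. Each other split mixes pXEN and XEN lines, which adds their difference to the spread within groups. Few gene calls there are thus built in and do not measure chance. Each count of the real split was reached by 1 of 10 splits, the real one, and 10 splits are too few for a share under 0.05.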

How the results depend on the processing

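The alternatives without Rn45s and without genes near 0 counts in pXEN were chosen after the data were seen. No paired analysis was possible because any 2 mouse groups share only the line number 2. Across alternatives 0 of the named genes and lists reversed direction where the main or the alternative fit passed the threshold. Counts among the main summary results could not reverse by their rule, and 0 of the rat similarity and score differences did. Among all called genes, 1 changed direction with unstranded counts in each comparison with ES. Of the main summary results 125 values stayed within the limit of change and 19 moved. For named genes 2814 values kept their sign and side of the threshold, 171 lost their call and 23 gained one. A further 28, past the threshold in neither fit, changed sign. For gene lists these were 699, 48, 18 and 19. DESeq2 called 155 genes higher in pXEN than XEN, against 100, and the cause was not tested. In the data simulated for this comparison DESeq2 made 19 calls among 10290 unchanged genes, against 2 by edgeR. It recovered 13 of 48 genes changed 2-fold, against 8. With an estimated correlation 2, 4 and 9 lists passed for pXEN against XEN, pXEN against ES and XEN against ES, against 12, 16 and 15. In pXEN against XEN the estimate exceeded the preset 0.01 for most lists that lost their call, up to 0.30 for cholesterol synthesis. It was below 0.01 for the trophoblast, Wnt and imprinted lists (-0.0687, 0.00435 and -0.00616), which also lost theirs. A higher correlation thus does not account for every loss. Fry, which tests against no change rather than against other genes, passed 13, 18 and 18 lists in these comparisons. In pXEN against XEN it passed pluripotency and anterior visceral endoderm (fry adjusted p = 0.0338 and 0.00687), which camera did not, and not cell cycle (0.281). Upper-quartile scaling shifted the median log2 fold change of all genes by -0.104 for pXEN and -0.112 for XEN against ES, so small changes are relative to the scaling. With sex as a covariate, calls between pXEN and XEN were lost for Dppa5a, Etv4, Id4, Igf1, Osmr, Runx1, Sfmbt2, Skil, Sp8, Tfap2a and Tnni3 among the named genes, and for Dkk1 between XEN and ES.

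The lead of pXEN over XEN in rat similarity, 0.0160, was 0.0175 by Pearson's r, 0.00950 over all shared genes, 0.214 over only genes that differ between pXEN and XEN (420 genes, chosen for that difference) and 0.00928 without genes near 0 in pXEN. The lead over ES, 0.0842, was 0.0516 over all shared genes and 0.107 over the differing genes. The score difference of XENP and ES, 3.43, was 6.23 with 50 genes per direction (exact permutation p = 0.0667), 2.28 without genes near 0 in pXEN (p = 0.2) and 2.40 without CX1 (p = 0.1). Causes were not tested beyond the choice of genes.

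Leaving out each line in turn gave 63 (XEN1) to 86 higher and 255 (pXEN2) to 362 lower genes in pXEN against XEN. It gave 1168 (ES2) to 1818 higher and 1358 to 1761 lower genes in pXEN against ES, and 1277 (ES2) to 2158 higher and 1197 (ES2) to 1834 lower genes in XEN against ES. Without ES3 the last counts were 1463 and 1262. Genes higher in both were 953 (ES2) to 1132, against 1672. Lists past the threshold were 9 to 13, 15 to 17 and 14 to 16. Fewer samples remain in these fits, and with an ES line left out the lone ES sample is assumed to vary like the other groups. In simulated data 2-fold changes were recovered for 16.7%, 4.17% and 8% of genes, so smaller changes were mostly missed there. The simulations held far fewer changed genes than the ES comparisons called, and may understate recovery in those. The smallest called absolute log2 fold change was 0.568 for pXEN and 0.544 for XEN against ES.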

Other observations

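The genes named first were chosen after their values were seen, and the test of X-linked genes was planned before its result was seen.

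Of the 100 genes higher in pXEN than in XEN, 43 were also higher in pXEN than in ES. H1f0, a linker histone, stood at 752 ± 214 CPM in pXEN, 268 ± 72.2 in XEN and 57.9 in ES (adjusted p = 0.0120 and 3.57e-05). The secreted chaperone gene Clu stood at 399 ± 118, 42.0 ± 28.7 and 6.20 CPM (9.48-fold and 64.0-fold, adjusted p = 0.0101 and 0.00047), and the growth factor gene Fgf10 at 90.8 ± 10.4, 27.1 ± 9.92 and 1.01 CPM (adjusted p = 0.00483 and 6.06e-06). Igf1 stood at 34.9 ± 17.9 and 7.11 ± 3.08 CPM with 0 ES counts, and Cyp26a1, which breaks down retinoic acid, at 25.2 ± 15.4 and 0.825 CPM with 2 ES counts. Without XEN1 the calls of Clu (adjusted p up to 0.0665), H1f0 (up to 0.0643) and Igf1 (up to 0.0797) against XEN were lost, and that of Igf1 also without XEN2.

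Female ES3 had little Xist (14.0 CPM), and a hypothesis was that both of its X chromosomes were active. The median log2 ratio of ES3 to male ES2 over 265 X-linked genes exceeded that over 7054 autosomal genes by 0.708, where random gene sets gave -0.0588 to 0.0547. The value is consistent with both X chromosomes being active, in 1 female and 1 male ES line. The like difference was 0.203 for pXEN6 against pXEN2 (Xist 150 CPM), above its random sets (-0.0512 to 0.0548). For pXEN4 against pXEN2 (Xist 784 CPM) it was 0.00756, within them (-0.0706 to 0.0672). For XEN1 (Xist 659 CPM) it was -0.0775 against XEN2, within its random sets (-0.0925 to 0.0813), and -0.0908 against XEN5, just below them (-0.0748 to 0.0753).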
